A study of Mus musculus with 48 samples.

How the data were processed

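The text rests on 22 peak lists, 1 for each of 22 of the 24 groups of 2 replicates that the labels give. The groups were taken from the labels, and FLAG in untreated WT cells and the IgG control were not analysed here. Cells were treated for 2 days with 500 µM IAA and 1 µg/ml doxycycline, per the labels. Per the submitters' processing notes, Trim Galore, Bowtie2, MACS2 and deepTools were used with the build mm10; versions and settings are not given in the sources used here. Each list pools replicates 1 and 2 by its title. The peak names inside most FLAG lists carry other replicate numbers, and for some genotypes the library codes differ between the FLAG and SMC3 lists, so which libraries a list holds rests on its title alone. As replicates are pooled, they cannot be compared, and cultures cannot be told from technical repeats.

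Each list has 5 columns without a header: chromosome, start, end, peak name and a value. The deposited value is a score of the authors' peak caller; which of the caller's measures it is could not be told, so it was compared only between peaks of the same list. FLAG lists repeat an interval for each summit, and these repeats were merged into 1 peak with the highest value; SMC3 and CTCF antibody lists have no repeats. Between 1.3% and 5.26% of peak numbers are missing from the running count in the names, so peaks were removed before deposit by a filter that the sources do not state. Some strong peaks may therefore be absent from a list. Depth per library is unknown, and the number of peaks in a list depends on it. Peaks on unplaced scaffolds and the mitochondrial genome were to be left out, but the SMC3 and CTCF antibody lists held none.

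Overlaps of at least 1 bp counted as shared. They were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the overlap function was checked against bedtools 2.31.1 and on simulated lists with known overlap. Figures were drawn with matplotlib 3.10.9. Shares have 95% Wilson intervals over peaks, which cover counting error only. Chance overlap was taken from lists shifted by 1 Mb in either direction. Differences over the 9 mutants were tested by exact two-sided sign-flip permutation, and correlations by two-sided permutation (all pairings for 9 or fewer values, 100000 resamples for 10) with Benjamini-Hochberg adjustment over 3 relations. Losses that 2 mutants share were measured by the phi coefficient within deciles of WT strength, and its relation to the distance between residues by a Mantel test with 100000 relabelings (10000 for leave-one-out). The sign-flip tests were not adjusted for one another.

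Genes came from the RefSeq table of GRCm38.p6, the assembly that mm10 names, with 34614 protein-coding and lncRNA spans. The table gives spans without strand, so, after this was seen, the planned distance to a transcription start was replaced by the distance to the nearest base of the span, and location by gene end (within 1 kb), gene body and intergenic; exon and intron are unknown. Named sites are those of a rule fixed before the data were examined. It takes the 8 strongest WT FLAG sites kept in all 9 mutants and the 8 strongest lost in at least 8. It takes the 8 strongest by summed rank that at least 5 mutants share outside the WT FLAG and CTCF antibody lists, where a list without the site counted as its length plus 1. It also takes, per mutant, the strongest WT site lost in it and the fewest others, the 5 strongest WT SMC3 sites at WT FLAG sites with no SMC3 in at least 8 mutants, and the 5 strongest untreated CTCF peaks without a treated peak. Last, it takes per gene list the member with the strongest WT FLAG site within 10 kb. Some sites that this rule takes are not reported here. Other list members named in the text were chosen after their values were seen. Each site is named by the nearest protein-coding gene. The lists were pluripotency, clustered protocadherin, Hox, imprinted, X inactivation centre, cohesin with its regulators and Ctcf, ribosomal protein, germline, and neural, mesoderm, endoderm and trophoblast lineage genes; every member matched a symbol in the table.

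Alternatives fixed before the data were examined were a reciprocal overlap of 50%, the upper 50% of each list by value, equal numbers of top peaks (3855 FLAG, 42030 SMC3 and 116973 CTCF antibody peaks), a match within 500 bp, standardisation over deciles of strength, leave-one-out over genotypes, Spearman rho and a 50 kb window. Alternatives chosen after seeing the data were WT sites with a treated CTCF antibody peak, the strongest untreated CTCF antibody peaks as reference, mutants tagged b1 only, and equal numbers of SMC3 peaks at lost and retained sites. The CTCF motif was not analysed here, since no genome sequence was used.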

Results

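CTCF is a zinc-finger DNA-binding protein that stops loop-extruding cohesin, and the series asks how single changes in its DNA-binding domain affect where it binds and where cohesin sits. Mouse embryonic stem cells of the E14Tg2a line carried an auxin degron on endogenous CTCF, a system in which 500 µM indole-3-acetic acid (IAA) is used to remove the protein, and a doxycycline-inducible Ctcf transgene that was either wild type (WT) or 1 of 9 mutants. The mutants were R339Q, R342C, S354F, K365T, R377C, R377H, Q418R, R448Q and H455R, named by residue. ChIPmentation, in which bound chromatin is tagged by a transposase during immunoprecipitation, was done with an antibody to FLAG for the transgene protein, to SMC3 for cohesin, and to CTCF itself in WT cells. The labels give 48 samples in 24 groups of 2 replicates, and 22 of these groups had a peak list: 10 FLAG, 10 SMC3 and 2 CTCF antibody lists. Each list pools both replicates, so each group gives 1 value, no spread between replicates can be had, and differences between single genotypes carry no p-value. The 95% Wilson intervals given in parentheses cover counting error over peaks only. Depth per library cannot be read from peak lists, and the labels state only an intended number of 150-bp paired-end reads.

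The FLAG lists differed widely in length. The WT transgene gave 15392 peaks, R377C gave 30462 and Q418R gave 30332, whereas H455R gave only 3855. The remaining FLAG lists held 13151 peaks in K365T, 16473 in R377H, 16687 in R342C, 18808 in R339Q, 19403 in R448Q and 24152 in S354F. SMC3 lists were longer, from 42030 peaks in Q418R to 153647 in R448Q, with 71962 in WT. The CTCF antibody gave 175815 peaks in untreated WT cells and 116973 in WT cells treated with IAA and doxycycline. Of the WT FLAG peaks, 91.1% (90.6 to 91.5) overlapped a CTCF antibody peak of treated cells and 81.2% (80.6 to 81.8) overlapped a WT SMC3 peak.

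CTCF binding in WT cells given IAA and doxycycline was compared with that in untreated cells through the CTCF antibody, which sees endogenous and transgene protein alike. Strong CTCF sites of untreated cells were nearly all present in treated cells, and weak ones were mostly not. Endogenous CTCF left after IAA was not measured, so these peaks cannot be assigned to the transgene alone. Of all untreated peaks, 56.9% (56.6 to 57.1) had a treated peak, against 7.88% when the treated list was shifted by 1 Mb. The share was 16.7% in the weakest decile of untreated peaks, 84.5% in decile 7 and 99.0% in decile 8. In the other direction, 91.7% (91.6 to 91.9) of treated peaks were found in untreated cells. With equal numbers of top peaks these shares were 75.3% and 84.2%, so the untreated list is longer but the gap between directions narrowed. The strongest untreated peaks without a treated peak lay nearest to Rplp1 (chromosome 9, 61723916 to 61725092, 188 kb away), which encodes a ribosomal stalk protein, and within the spans of Mga (chromosome 2, 119880773 to 119880963), Yy1 (chromosome 12, 108819109 to 108819798), Map3k19 and Nuf2, a kinetochore component. The Rplp1 site nevertheless held a WT FLAG peak and FLAG peaks in 8 mutants, while the Mga, Yy1, Map3k19 and Nuf2 sites held no FLAG peak in any genotype.

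**Figure D1:**
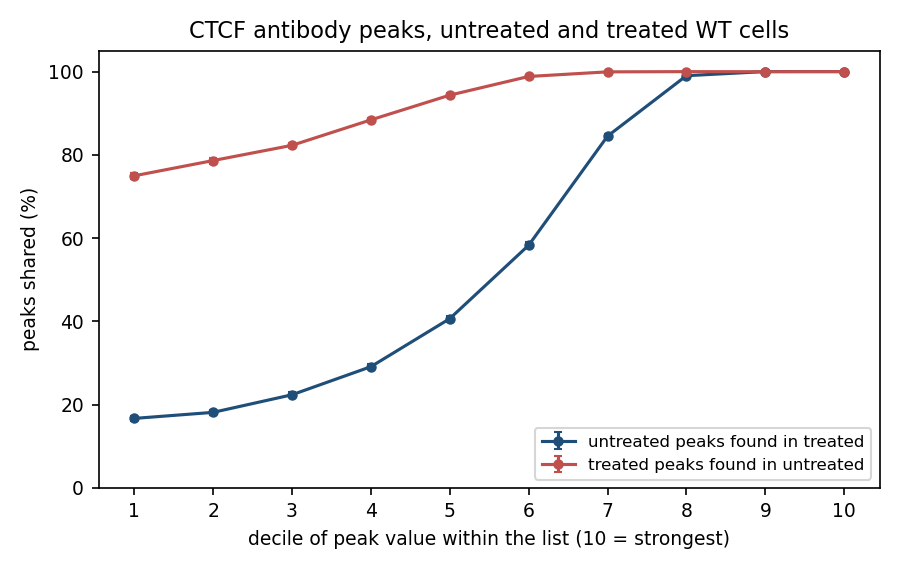
Share of CTCF antibody peaks (y axis, %) of untreated WT cells found in treated WT cells, and the reverse, by decile of peak value within the list (x axis). Error bars are 95% Wilson intervals over peaks; untreated peaks rise from 16.7% shared in decile 1 to 99.0% in decile 8.

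Each mutant was then compared with the WT transgene at the 15392 WT FLAG sites. R377C and S354F kept most of them, 89.6% (89.1 to 90.1) and 86.2% (85.6 to 86.7). R448Q kept 75.2% (74.5 to 75.9), R342C 72.2% (71.5 to 72.9) and R377H 71.8% (71.1 to 72.5). Q418R kept 59.2% (58.5 to 60.0), R339Q 53.1% (52.3 to 53.9) and K365T 52.1% (51.3 to 52.9), and H455R 1611 of 15392 sites, 10.5%. Shifting the mutant list by 1 Mb gave between 0.12% (H455R) and 1.53% (R377C). The share that a second list of the WT transgene would keep is unknown, so sites not kept cannot all be put down to the mutation. Of the strongest untreated CTCF antibody peaks, the WT FLAG list held 66.8%, R342C 64.9%, R448Q 64.8% and R377H 61.6%. R377C (87.5%) and S354F (85.5%) held more, and Q418R (54.0%), R339Q (52.7%), K365T (44.0%) and H455R (8.06%) less. The list lengths differ with the mutant: with the 3855 strongest peaks of each list, Q418R kept 29.9%, S354F 56.8% and H455R 17.3%. The order of mutants depended on the overlap asked for. Under a reciprocal overlap of 50% R377C kept 35.1%, less than R342C at 60.0%. R339Q fell to 22.9%, Q418R to 37.8% and S354F to 53.0%, while K365T was at 41.2%. H455R was lowest under every alternative tried. A reciprocal overlap also depends on peak width, and the median FLAG width was 250 bp in WT, 312 bp in R377C and 294 bp in R339Q. It was 318 bp in S354F and 200 bp in R342C. A lower share under this setting need not mean fewer sites bound.

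Retained WT sites had a higher median WT peak value than lost ones in all 9 mutants. The median WT peak value of retained sites exceeded that of lost sites by 1.2 on the caller's scale on average (SD 0.205, n = 9 mutants; exact two-sided sign-flip permutation p = 0.00391, the smallest that 512 sign flips allow). All 9 mutants share the same WT list, so they are not independent, which this p does not account for. The CTCF antibody lists of untreated and treated WT cells also shared strong peaks more often than weak ones. The sign is therefore not particular to the mutants. In the strongest quartile of WT sites, R377C kept 99.8%, S354F 98.8%, R448Q 97.3%, R342C 97.0% and R377H 96.4%. K365T kept 85.8%, Q418R 83.4% and R339Q 75.4% of that quartile, and H455R 17.3%. In the weakest quartile the range ran from 8.63% in H455R to 71.9% in R377C. In H455R the share did not rise steadily with strength, at 7.09% in the second quartile and 8.84% in the third.

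**Figure D2:**
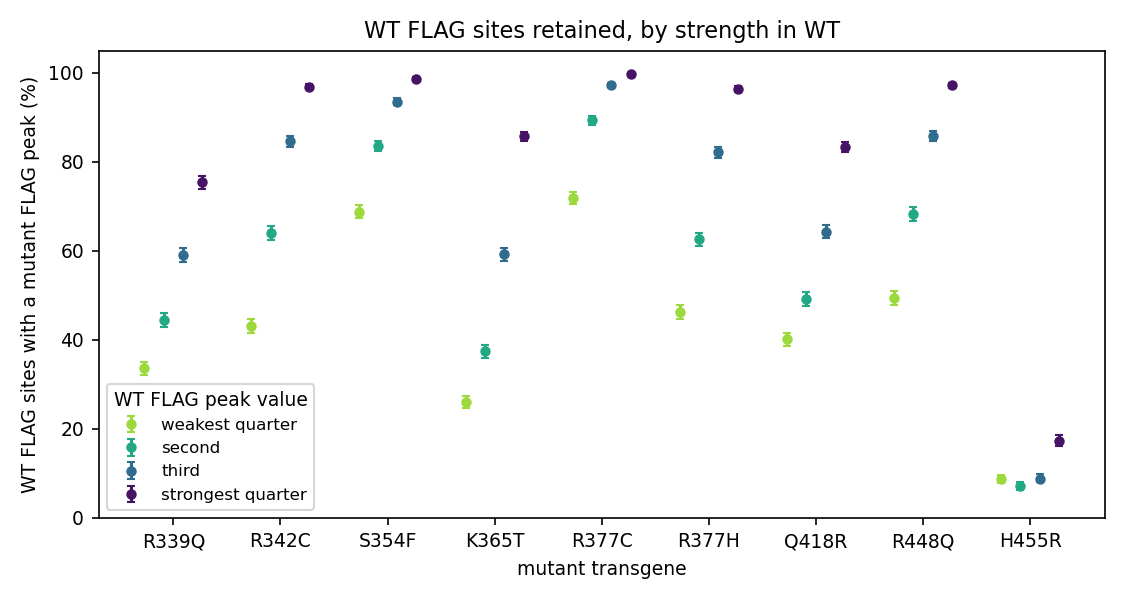
Share of WT FLAG sites with a FLAG peak in each mutant (y axis, %), by quartile of WT peak value (colours), for the 9 mutants (x axis). Error bars are 95% Wilson intervals over sites; H455R lies between 7.09% and 17.3% in all quartiles, and R377C reaches 99.8% in the strongest.

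The 775 WT FLAG sites kept by all 9 mutants included strong sites within Cyria (chromosome 12, 12322808 to 12324023), which encodes a RAC1-interacting protein, next to Id2 (chromosome 12, 25092043 to 25092920), an inhibitor of helix-loop-helix transcription factors, and within Cep120 (chromosome 18, 53744507 to 53744949), which encodes a centriole protein. Others were nearest to Setd4, Dmrt3, Ccdc60 and Tmem45b. Each of these sites had both CTCF antibody peaks and an SMC3 peak in WT and in all 9 mutants. Of sites retained in all mutants, 95.7% had a WT SMC3 peak. At the other end, 738 WT sites were lost in all 9 mutants; 6.37% of them overlapped a CTCF antibody peak and 5.69% a WT SMC3 peak. The strongest sites lost in at least 8 mutants lay near Tns1 (chromosome 1, 73902458 to 73902677), within Cdh12, and far from any protein-coding gene with Psat1, Bambi and Khdrbs3 as the nearest, all outside both CTCF antibody lists, and within Slc35f3 (chromosome 8, 126267195 to 126267559) and Sema5a (chromosome 15, 32246126 to 32246281) and nearest to Pfkp, all inside both.

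Some WT sites, not all of them strong, were lost in a single mutant. A site nearest to Arpp21 (chromosome 9, 111918588 to 111918943) was missing only in R339Q, and a site nearest to Lmcd1 (chromosome 6, 112197403 to 112197857) only in Q418R. A site nearest to Drd1, the dopamine receptor gene, was missing only in K365T, one nearest to Rtl9 only in S354F, one beside Adrm1, which encodes a proteasome ubiquitin receptor, only in R448Q, and one nearest to Cemip2 (chromosome 19, 21747131 to 21748205) only in H455R. For R377C and R377H the sites with the fewest other losses, in Tll2 and nearest to Lpar3, were also missing in R339Q. SMC3 peaks were present in all 9 mutants at the Arpp21, Lmcd1, Adrm1 and Cemip2 sites. At the Lpar3 site SMC3 was missing in R339Q and R377H, the mutants without FLAG there, and at the Rtl9 site in S354F and R377C. At the Drd1 and Tll2 sites it was missing only in mutants other than those the site was chosen for.

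The substitutions R377C and R377H, at the same arginine, gave lists of different length, 30462 and 16473 peaks. With overlaps of 1 bp they shared 11007 WT sites (71.5%), R377C alone kept 2790 (18.1%) and R377H alone kept 51 (0.331%). The direction depended on the setting: with equal numbers of top peaks R377C kept 67.0% and R377H 62.4% of WT sites, and under a reciprocal overlap of 50% R377H kept more, 53.5% against 35.1%. A reciprocal overlap depends on peak width, and the median FLAG width was 250 bp in WT, 312 bp in R377C and 276 bp in R377H. Of all R377H FLAG peaks, 90.1% overlapped an R377C peak. No test of this difference was possible with 1 list per mutant.

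FLAG peaks of the mutants outside the WT FLAG list made up 70.2% (69.7 to 70.8) of the Q418R list, 58.1% of H455R, 57.4% of R339Q and 55.9% of R377C. They were 45.8% in S354F, 40.6% in R448Q, 39.0% in K365T, 33.6% in R377H and 33.0% in R342C. Most of them lay at CTCF antibody peaks in S354F, at 91.3% (90.8 to 91.8), and R377C, at 83.9% (83.4 to 84.5). The share was 54.5% (53.8 to 55.1) in Q418R and 33.3% (31.4 to 35.3) in H455R. With equal numbers of top peaks the R377C share outside WT was 33.6%. Sites present in at least 5 mutants and in neither the WT FLAG nor a CTCF antibody list numbered 125 of 12592. The strongest lay within Kyat1 (chromosome 2, 30203305 to 30204009), found in 8 mutants and with a WT SMC3 peak, and at a pair of places within Plekhh2, with others in Arhgef33, Cdh13, Camkmt, Tmem14a and Tmem132b.

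Cohesin was followed at the 12503 WT FLAG sites with a WT SMC3 peak. SMC3 peaks were kept at 97.9% (97.7 to 98.2) of them in R448Q, 96.6% (96.2 to 96.9) in R342C, 91.3% in R377H, 89.9% in K365T and 87.3% in R377C. The share was 81.4% in S354F, 78.0% in R339Q, 77.9% in H455R and 74.1% (73.4 to 74.9) in Q418R. The order turned under a reciprocal overlap of 50%, where R448Q was lowest at 44.6% and R377H highest at 69.8%. That overlap depends on peak width, and the median SMC3 width was 222 bp in WT, 280 bp in R448Q and 233 bp in R377H. At the 37373 WT SMC3 peaks away from every WT FLAG and CTCF antibody peak, the share kept ranged from 14.5% in Q418R to 70.1% in R448Q, the shortest and the longest mutant SMC3 list. With equal numbers of top SMC3 peaks the range was 22.1% in Q418R to 49.8% in R342C. Of WT FLAG sites with WT SMC3, 7017 (56.1%) had SMC3 in all 9 mutants and 134 in at most 1. The strongest of the latter lay within Rbfox1 (chromosome 16, 6503646 to 6503846), a splicing factor gene, Grk5 (chromosome 19, 60892225 to 60892400) and Dpp6, and nearest to Gm46752 and Plod2.

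With overlaps of 1 bp, SMC3 was found in all 9 mutants more often where the mutant FLAG peak was retained than where it was lost. The difference averaged 26.3 percentage points (SD 15.8, n = 9 mutants, range 7.6 to 56.0; exact two-sided sign-flip permutation p = 0.00391), with the same limit that the mutants share 1 WT list. Standardised over deciles of WT FLAG strength the mean was 24.4 percentage points. Sites were not matched on WT SMC3 strength, and in the FLAG and CTCF antibody lists strong peaks recurred more often than weak ones. A positive difference therefore need not mean that cohesin follows CTCF. Under a reciprocal overlap of 50% the mean was 12.9 percentage points (exact permutation p = 0.0117), positive in 8 of 9 mutants, with R448Q at -0.648 and R342C at 0.499. SMC3 stayed at 91.7% of lost sites in R448Q, 87.6% in R342C, 77.9% in K365T, 76.2% in H455R and 75.4% in R377H. It stayed at 63.6% in R377C, 55.8% in R339Q, 46.7% in Q418R and 28.4% in S354F. The lost sites with WT SMC3 are a different set in each mutant, from 360 in R377C and 652 in S354F to 11238 in H455R. The mean difference weighs the mutants equally. Peak names in the SMC3 lists carry a tag whose meaning is not stated: b1 alone in WT, R342C, K365T, R377H, R448Q and H455R, and b2 or b3 in the other 4 mutants. Of these, R339Q carries b2 alone, Q418R b3 alone, and S354F and R377C both b1 and b2. Within the 5 mutants tagged b1 alone the difference was 15.3 percentage points (SD 5.71, positive in 5 of 5), where the smallest exact p is 0.0625. The other tags, or the mix of b1 and b2, hold at most 2 mutants each, too few for a value of their own.

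**Figure D3:**
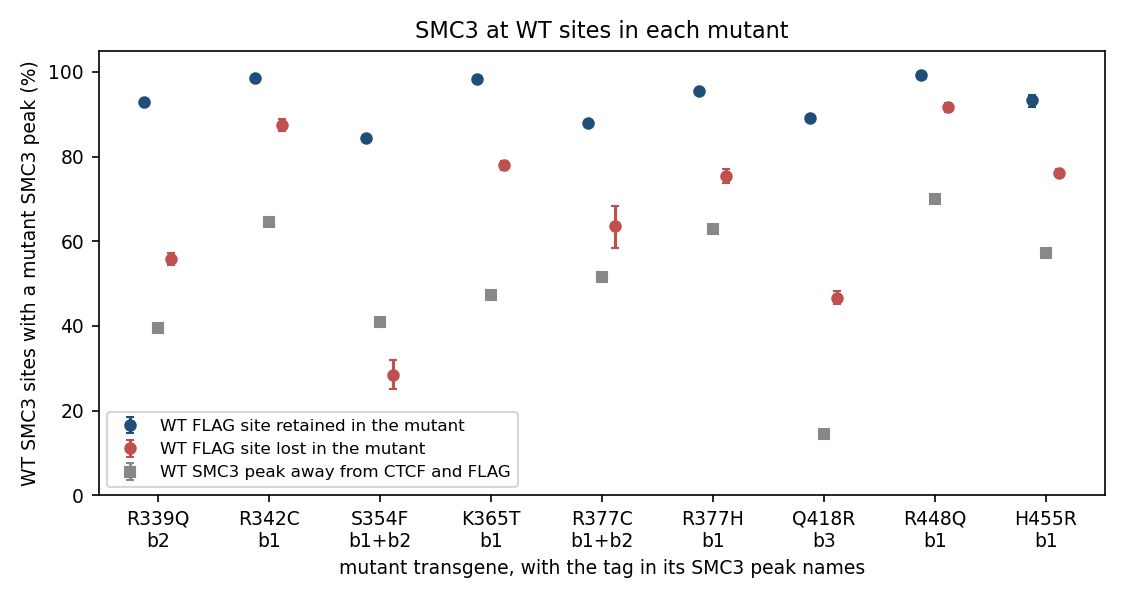
Share of WT SMC3 sites with an SMC3 peak in each mutant (y axis, %), for WT FLAG sites retained or lost in that mutant and for SMC3 peaks away from CTCF and FLAG (symbols); mutants and the tag in their SMC3 peak names are on the x axis. Error bars are 95% Wilson intervals over sites; retained sites lie above lost sites in all 9 mutants with overlaps of 1 bp, and in 8 under a reciprocal overlap of 50%, which is not drawn.

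Across genotypes, 3 relations were tested. FLAG peak number and SMC3 peak number gave r = -0.286 (permutation p = 0.424, adjusted p = 0.424) and rho = -0.0424 (permutation p = 0.918, adjusted p = 0.918) over 10 genotypes, -0.485 without H455R and R377C, and r = 0.461 (exact permutation p = 0.347) within the 6 genotypes tagged b1. The share of WT FLAG sites retained and the share of SMC3 kept there gave r = 0.441 (exact permutation p = 0.241, adjusted p = 0.361) and rho = 0.417 (exact permutation p = 0.27, adjusted p = 0.404) over 9 mutants, and r = 0.409 without H455R and K365T. The 5 mutants tagged b1 alone are fewer than the 6 set as the minimum for a correlation. Their order was the same on both measures with overlaps of 1 bp and full lists, but not with equal numbers of top peaks or under a reciprocal overlap of 50%. FLAG peak number and the share of SMC3 peaks holding a FLAG peak of the same genotype gave r = 0.795 (permutation p = 0.00847, adjusted p = 0.0254), with rho = 0.564 (permutation p = 0.0962, adjusted p = 0.289), and r = 0.826 without H455R and R377C. Within the tag b1 that r was 0.658 (exact permutation p = 0.21), so the relation did not pass the threshold within a tag. A positive r is built into this measure, since the number of FLAG peaks bounds the share of SMC3 peaks that can hold one, so it shows no relation beyond list length.

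Location was described through the share of WT FLAG sites within 1 kb of either end of an annotated gene, for which no test was planned. Lost sites had a lower share than retained ones in all 9 mutants, with a mean difference of -4.58 percentage points (SD 3.23, n = 9 mutants) and a range of -9.96 to -2.08. The gap was widest in S354F and R377C, and in R448Q the share was 12.7% of lost and 14.8% of retained sites. All mutants share the WT list, in which peaks outside both CTCF antibody lists had a share of 4.08% against 15.3% for those inside. Of the sites lost in R377C, 79.6% had no treated CTCF antibody peak, and in S354F 57.0%. Among WT sites with such a peak, the mean difference was -2.19 percentage points (SD 3.73), negative in 7 mutants and positive in R342C and R448Q.

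Gene groups fixed before the data were examined were compared through the WT FLAG sites within 10 kb of their members. The share retained was set against 10000 random sets of WT FLAG sites matched on strength, as a description without a p-value. The random sets were not matched on CTCF antibody peaks or on nearness to genes. With 8 lists in 9 mutants looked at, some extreme percentiles arise by chance. The clustered protocadherins, cell-surface cadherins whose promoter choice depends on CTCF, had 23 WT sites near 45 of 57 genes, kept at 62.8% on average (percentile 20.4). R339Q kept 2 of 23 of these sites (percentile 0), R342C 12 of 23 (percentile 0.15) and H455R 1 of 23 (percentile 16.8), whereas R377C kept 23 of 23 (percentile 93.1), Q418R 18 of 23 (percentile 95.5) and K365T 16 of 23 (percentile 92.5). R448Q and S354F kept 20 of 23 each and R377H 18 of 23, at percentiles between 37.3 and 83.6. All 23 sites lie on chromosome 18 between positions 36945910 and 37765991, whereas the random sets were drawn from all WT sites. Neighbouring sites are thus counted as independent, and the percentiles may overstate how unusual the group is. In the Pcdhg cluster K365T kept 11 of 11 sites but in the Pcdhb cluster 2 of 8. The strongest site of the group, in Pcdhga1 (chromosome 18, 37751186 to 37751754), was kept in 8 mutants, all but H455R, and had SMC3 in all 9. Elsewhere SMC3 was found in 1 or 2 mutants at the strongest sites near Pcdha genes, in 6 at that near Pcdhb2 and in 9 at that near Pcdhga12.

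**Figure D4:**
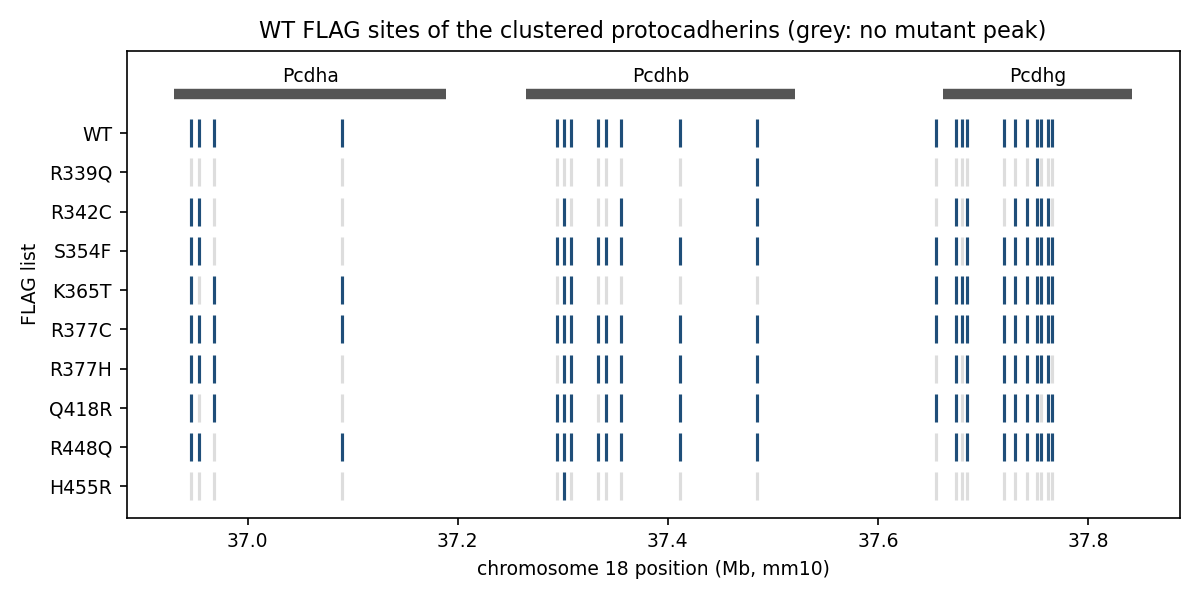
WT FLAG sites within 10 kb of the clustered protocadherin genes on chromosome 18 (x axis, Mb, mm10), with a row per FLAG list; blue ticks are WT sites with a peak in that list and grey ticks those without, drawn at the site centre and not to peak width. Grey bars at the top span the Pcdha, Pcdhb and Pcdhg genes; R339Q holds 2 of 23 sites and R377C 23 of 23.

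Sites near ribosomal protein genes were kept more often than strength-matched sites: 74.0% on average over mutants, at percentile 100. These sites were chosen for lying near genes, and retained WT sites lay at gene ends more often than lost ones in all 9 mutants. Whether the excess goes beyond that of sites near genes in general was not tested. R377C and S354F kept 44 of 44 each, R377H 39 of 44 and R339Q 33 of 44, and in 6 mutants the percentile was 98.6 or higher. The strongest of these sites, near Rps16 (chromosome 7, 28344609 to 28345003), was kept in 8 mutants, as were those near Rps10 and Rps19, while the strongest near Rps2 and Rps4x were kept in 3. Sites near pluripotency genes were kept at 70.1% on average (percentile 90.6, 13 sites). The strongest site near Sox2 (chromosome 3, 34640740 to 34641050), a core pluripotency transcription factor gene, was kept in all 9 mutants, the strongest near Pou5f1, Sall4 and Tbx3 in 8, the one near Nanog in 6, and the strongest near Esrrb and Dnmt3l in 2. Sites near Hox genes were kept at 69.0% on average (percentile 82.7); in R339Q 5 of 14 were kept. The strongest lay in Hoxa3 (chromosome 6, 52204423 to 52204857) and was kept in 8 mutants, while the strongest near Hoxa9 and Hoxa10 was kept in 9 and that near Hoxd11 and Hoxd12 in 2.

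Sites near imprinted genes were kept at 63.0% on average (percentile 37.7, 24 sites), with R448Q at 13 of 24 (percentile 0.345). The strongest near Usp29 (chromosome 7, 6940742 to 6941181), Airn, Cdkn1c and Trappc9 were kept in 8 mutants, the one near Meg3 in 9 and the strongest near Zim1 in 3. Sites near genes of cohesin, its regulators and Ctcf were kept at 68.9% (percentile 78.6); that in Pds5b (chromosome 5, 150673524 to 150673910) was kept in 7 mutants and that near Smc3 in 8. Mesoderm genes gave 72.2% (percentile 54.0, 6 sites, with the Tbx6 site at chromosome 7, 126779990 to 126780296 kept in 4 mutants) and trophoblast genes 66.7% (percentile 25.1, 7 sites, with the Elf5 site at chromosome 2, 103445664 to 103446191 kept in 8); both positions turned with a 50 kb window, to percentile 28.5 and 84.5. Germline genes had 3 sites, neural genes 2, endoderm genes 2 and the X inactivation centre 0, fewer than the 5 needed for a percentile. The strongest of these, near Tex101 (chromosome 7, 24662494 to 24662978) and in Neurog2 (chromosome 3, 127634097 to 127634446), were kept in 8 mutants and that near Gata4 (chromosome 14, 63195902 to 63196007) in 5.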

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

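The tests of library batch, of a less sensitive WT list and of sites off the CTCF antibody lists were chosen only after the results they measure had been seen, as was the baseline of the Q418R SMC3 list, and the grouping by tag was noticed after the SMC3 values.

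With full lists and overlaps of 1 bp, H455R kept 10.5% of WT FLAG sites, a value set apart from the other 8 mutants. The nearest of these was K365T at 52.1%, a gap of 0.526 of the range, where 0.493 was needed. Chance sets about 1 in 20 such groups apart, and 11 measures were looked at. With equal numbers of top peaks H455R kept 17.3%, the nearest mutant, Q418R, 29.9% and the highest, R377C, 67.0%. Under a reciprocal overlap of 50% H455R kept 6.65%, the nearest, R339Q, 22.9% and the highest, R342C, 60.0%. H455R stayed lowest under these settings, but the gap was too small a part of the range to set it apart.

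The 4 mutants with b2 or b3 in their SMC3 peak names had SMC3 at 48.6% of lost FLAG sites on average (SD 15.2), against 81.8% (SD 7.39) in the 5 tagged b1 alone. Equal list lengths did not remove the gap: with equal numbers of top SMC3 peaks it was 29.2 percentage points (exact permutation p = 0.00794). That p is the smallest that groups of 5 and 4 mutants allow. The tags were grouped after the SMC3 shares had been seen, so no p-value for this grouping counts as a test of it. A library batch may contribute. The mutants with b2 or b3 were also lower by 23.7 percentage points at WT SMC3 peaks away from CTCF (exact permutation p = 0.0238). With equal numbers of top SMC3 peaks they were lower there by 14.3 (exact permutation p = 0.0238), less than the gap at lost sites. S354F and R377C carry b1 beside b2, and had the lowest and highest shares of the 4, 28.4% and 63.6%. Lost sites are also a different set in each mutant. Of all sites lost in R377C 79.6% had no treated CTCF antibody peak, and in S354F 57.0%, against 7.66% in H455R. The averages therefore compare unlike sets of sites. The meaning of the tag is not stated, WT carries b1, and tag and mutant cannot be separated, so an effect of these mutations on cohesin stays open and untested.

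In Q418R, 33.2% of FLAG peaks lay outside both CTCF antibody lists, against 8.76% in WT and 46.7% in the much shorter H455R list. By the rules written before, a background shared by the FLAG lists and signal at gene ends are both argued against. Of the Q418R peaks outside, 2.78% overlapped 3 or more other FLAG lists, against 3.43% (R339Q) to 25.8% (S354F) in other genotypes. Shorter lists would miss weak background peaks, so such a background cannot be excluded. The share of these Q418R peaks at gene ends differed from that of the other Q418R peaks by -7.97 percentage points. Yet at 10.2% it exceeded the share of outside peaks in every other genotype but R339Q (20.8%). For sites of its own that hold cohesin, SMC3 in Q418R was at 1.05 times the median of the other 9 genotypes there. So low a ratio argues against this explanation by the rule written before. It is kept open here only because of the SMC3 baseline, which was looked at afterwards. The Q418R SMC3 list, the only one tagged b3, was low away from CTCF. There it kept 22.1% of WT SMC3 peaks at equal numbers, against 31.9% to 49.8% in the other mutants. At equal numbers it was mid-range at retained WT FLAG sites, with 90.3% against 80.4% to 97.6% in the other mutants. At lost sites it had 48.7%, lower than most mutants but above S354F at 22.8%. Its baseline therefore differs between kinds of site and does not settle the question. Weak peaks near the caller's limit may account for most, since 6.12% of the strongest quartile of Q418R peaks lay outside, although in WT that share was 0.286% and in H455R 15.6%. What sets the stronger of these peaks apart stays open.

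R377C and S354F had more FLAG peaks than WT. A WT list of lower sensitivity may be the cause: of the strongest untreated CTCF antibody peaks, S354F, the lower of the pair, held a share 18.8 percentage points above that of WT. Sites off the CTCF antibody lists are argued against, since at most 16.1% of their FLAG peaks outside WT lay outside both lists. Stronger binding or higher expression of these mutants would give the same pattern, and no biological explanation was tested. Q418R, R448Q, R339Q, R342C and R377H also had more FLAG peaks than WT. They held 52.7% to 64.9% of the strongest untreated CTCF antibody peaks, less than WT at 66.8%.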

How the results depend on the processing

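Tests on WT sites with a treated CTCF antibody peak, on the strongest untreated peaks as reference, on the tag b1 alone and on equal numbers of SMC3 peaks at lost and retained sites were chosen only after the results were seen. No paired analysis was possible because each list pools replicates 1 and 2. The motif alternatives were not run. Where a value moved, the cause was not tested. Depth per library is unknown, so a missing peak may be a site below the caller's limit. Equal numbers of top peaks drop peaks that were called, so that setting does not show such a limit. With it, WT sites retained fell to 29.9% in Q418R and to 67.0% in R377C, whose lists are of like length.

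With a reciprocal overlap of 50%, WT FLAG sites retained were R339Q 22.9%, R342C 60.0%, S354F 53.0%, K365T 41.2%, R377C 35.1%, R377H 53.5%, Q418R 37.8%, R448Q 60.0%, H455R 6.65%. FLAG peaks outside WT were R339Q 81.3%, R342C 44.6%, S354F 66.2%, K365T 51.8%, R377C 82.3%, R377H 50.0%, Q418R 80.8%, R448Q 52.4%, H455R 73.5%. SMC3 kept was R339Q 49.3%, R342C 61.6%, S354F 51.4%, K365T 68.7%, R377C 65.0%, R377H 69.8%, Q418R 47.8%, R448Q 44.6%, H455R 60.8%, and 36.2% of untreated CTCF antibody peaks and 54.4% of treated ones were shared. R342C, closely followed by R448Q, and not R377C then kept the largest share of WT FLAG sites, and R448Q the lowest share of SMC3. With the upper 50% of each list, retained shares were R339Q 54.8%, R342C 73.4%, S354F 82.6%, R377C 95.3%, Q418R 57.7%, R448Q 76.9%, H455R 8.99%, shares outside WT R339Q 55.7%, R342C 32.1%, S354F 47.7%, R377C 52.5%, R377H 32.7%, Q418R 70.9%, R448Q 39.2%, H455R 64.0%, and SMC3 kept R339Q 81.9%, R342C 97.7%, K365T 93.4%, R377C 89.1%, R377H 93.6%, Q418R 79.4%, R448Q 98.8%, H455R 83.2%; 66.5% of untreated CTCF antibody peaks and 98.0% of treated ones were shared. With equal numbers of top peaks, retained shares were R339Q 42.4%, R342C 63.7%, S354F 56.8%, K365T 51.0%, R377C 67.0%, R377H 62.4%, Q418R 29.9%, R448Q 59.9%, H455R 17.3%, shares outside WT R342C 36.3%, S354F 43.3%, K365T 49.0%, R377C 33.6%, R377H 37.8%, H455R 82.6%, and SMC3 kept R339Q 72.4%, R342C 93.7%, S354F 77.8%, K365T 87.0%, R377C 82.0%, R377H 86.1%, Q418R 75.9%, R448Q 93.8%, H455R 71.8%; 75.3% of untreated CTCF antibody peaks and 84.2% of treated ones were shared. A match within 500 bp gave R339Q 54.3%, R342C 73.4%, S354F 87.0%, K365T 53.4%, R377H 72.7%, Q418R 60.7%, R448Q 76.2%.

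At WT sites with a treated CTCF antibody peak, retained shares were R339Q 58.1%, R342C 78.9%, S354F 93.5%, K365T 55.4%, R377C 97.7%, R377H 78.2%, Q418R 62.2%, R448Q 81.0%, H455R 9.26%. With the strongest untreated CTCF antibody peaks in place of the WT FLAG sites, the WT FLAG list itself held 66.8% of them, and the mutant lists held R342C 64.9%, S354F 85.5%, K365T 44.0%, R377C 87.5%, R377H 61.6%, Q418R 54.0%, R448Q 64.8%, H455R 8.06%. H455R kept the lowest share under all 6 of these alternatives.

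The mean difference in SMC3 between retained and lost sites stayed positive and past the threshold with standardisation over deciles (24.4 percentage points), a reciprocal overlap of 50% (12.9, where R448Q turned to -0.648), the upper 50% of each list (19.7), equal numbers of SMC3 peaks (32.2) and leave-one-out over mutants (22.5 to 28.6). With the tag b1 alone it was 15.3 percentage points, with an exact permutation p of 0.0625, the smallest that 5 mutants allow. The r of FLAG and SMC3 peak numbers, never past the threshold, ran from -0.409 to 0.055 under leave-one-out and turned to 0.461 with the tag b1 alone and 0.055 without Q418R. The r of FLAG peak number and the share of SMC3 peaks with a FLAG peak was 0.658 with the tag b1 alone, no longer past the threshold with 6 genotypes, and rho was 0.564, also not past it. Under leave-one-out the Mantel r ran from -0.731 without R448Q to -0.206 (permutation p = 0.312) without H455R and was -0.371 (permutation p = 0.0506) at WT sites with a treated CTCF antibody peak. The gene-end difference was -2.19 percentage points at those sites, with R342C and R448Q turned. With a 50 kb window, 10 gene lists had enough sites, and their mean retained share ran from 60.8% (imprinted) to 82.2% (neural, 5 sites, percentile 99.1), with germline at 67.2% (percentile 86.6). The percentile turned to 84.5 for trophoblast (76.3%) and to 28.5 for mesoderm, and was 100 for ribosomal protein genes (70.3%).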

Other observations

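The tests on WT sites with a treated CTCF antibody peak were chosen only after the results were seen.

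Mutants lost overlapping sets of WT sites. All 9 lost 738 WT FLAG sites, against 16.3 on average in 100 draws of independent losses within strength deciles, and all 9 kept 775 against 408. All mutants share the WT list, and only 6.37% of the sites lost in all overlap a CTCF antibody peak. Among the 14023 WT sites with a treated CTCF antibody peak, 43 were lost in all against 0.24. The pair S354F and R377C, 23 residues apart, had the highest phi of lost sites, 0.445, followed by R377H and R448Q, 71 residues apart, with 0.433, and R339Q and R342C, 3 apart, with 0.404. R448Q and H455R, only 7 apart, had 0.0682. R377C and R377H, at the same residue, ranked 5 of 36 pairs with 0.353, against a median of 0.235. R377H also lost 1544 of the 1595 sites lost in R377C. Part of any excess over the median may come from the shared WT list. At WT sites with a treated CTCF antibody peak the Mantel r below was -0.371.

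A hypothesis, written before its result was seen, was that mutants at neighbouring residues lose the same WT sites. The Mantel r between residue distance and phi was -0.478 (permutation p = 0.0112, n = 9 mutants). Without H455R it was -0.206 (permutation p = 0.312), so the relation rests on H455R. That mutant lost 13781 of 15392 sites, which limits its phi with every other mutant. These data do not decide the hypothesis. Its written prediction asked only for the first of these p-values; the demand that the relation hold without each mutant was added after the leave-one-out values were seen.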
